A study of Homo sapiens with 24 samples.

How the data were processed

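Gene expression was measured by sequencing of polyadenylated RNA from A549 cells transduced with a GPD1 lentivirus or a blank lentivirus, with 10 mM metformin or without it, in 3 labelled replicates of each of 4 groups. Libraries were made with an NEBNext Ultra kit, per the labels' protocols, which state no strand, so overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.1.0 and edgeR (no version given) were used and GRCh38/hg38 is named. The program that made the values and its gene annotation are not given in the sources used here. The deposited table holds 58302 genes by 12 columns of FPKM as the authors computed them, although its header names no unit. FPKM was inferred from the values, which are not whole numbers and whose low values, multiplied by the merged exon length of the gene, are whole multiples of 1 step per column within 0.02 for 64.9% to 69.6% of genes with up to 10 steps. The same values could be RPKM. The steps correspond to 13.3 to 18.0 M reads or fragments per library, and 1 read on 1 kb is worth 0.0556 to 0.0753 FPKM. Merged exon lengths came from GENCODE release 29, which gives the same locus for 97.1% of the genes and a length for 99.5%.

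Each library was assigned to its group from its column label. The 12 libraries of 786-O cells were not analysed here. The groups, 5 comparisons, 30 gene lists and the main alternatives were fixed before the data were examined. The plan was for read counts. As the table holds FPKM, the test set down for that case was used, on log2(FPKM + 1) in limma 3.58.1 (R 4.3.3) with an intensity trend. Genes with a mean of at least 1 FPKM over the 12 libraries were tested (12607 genes), in a model of 4 group means. Each comparison was adjusted by Benjamini and Hochberg, with a threshold of 0.05. The comparisons were metformin against none in vector cells and in GPD1 cells, GPD1 against vector without and with metformin, and the interaction. With the pseudocount of 1, fold changes of weakly expressed genes are understated.

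The lists covered glycerolipid synthesis, the malate-aspartate shuttle, glycolysis, the TCA cycle, complex I nuclear subunits, mitochondrial genome transcripts, fatty acid synthesis and oxidation, cholesterol synthesis and uptake, hypoxia response, ATF4 stress response, serine and one-carbon synthesis, aminoacyl-tRNA synthetases, amino acid transporters, ER chaperones, DNA replication, mitosis, p53 targets, NRF2 targets, NF-kB and cytokines, interferon response, autophagy and lysosome, cytosolic ribosomal proteins, ribosome biogenesis, mesenchymal and epithelial genes, metallothioneins, polyadenylated histone transcripts, and lung and kidney lineage genes. GPD1 was left out of every list. Lists were tested with camera, which compares a list with all other tested genes, with a preset correlation of 0.01, and adjusted over the 30 lists of a comparison. The alternatives were a correlation estimated from the data and fry. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes, and it called every list that camera called. Where most genes change, as with metformin, a call by fry therefore adds little to one by camera. Ribosomal protein genes have many processed copies in the genome, and how reads on such copies were assigned is not given.

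Genes were named by rule. GPD1 was always named, with up to 8 protein-coding genes per direction that had the largest changes among those with an adjusted p under 0.05, a mean of at least 5 FPKM and no overlap between the libraries of the groups compared (not asked for the interaction). Of each called list, the 3 genes with the smallest p in the direction of the list were added. Y-linked genes were not named, and genes with only a clone name were passed over. Genes named outside this rule are given as such.

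Alternatives were scaling by median-ratio or upper-quartile factors, no filter, a pseudocount of 0.1, a fit of only the groups compared, replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. After the first results 5 more were added, namely totals taken without mitochondrial genes, removal of a transcript length trend or of a GC trend per library (natural splines with 5 degrees of freedom), protein-coding genes alone, and omission of genes whose FPKM + 1 differed at least 5 times between libraries of a group. Windows of 25 neighbouring tested protein-coding genes (at least 15) of the autosomes and the X chromosome were compared with 1000 shuffles of gene order. Windows were marked from a median of 0.25. The test was run on simulated data, with 50 genes each changed 1.5, 2, 3 and 4 times among 12607. Noise was drawn independently for each gene. The test recovered 72%, 80%, 94% and 98% with 10 false calls among 182. A list whose genes were all shifted by the same amount was called and 0 others were. With few changed genes and no correlation between genes, the simulation does not test list calls in these data. Nor does it test counts where most genes change, as with metformin. Pearson's r between replicates was 0.989 to 0.991 on the log2 scale. Figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.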

Results

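Polyadenylated RNA was sequenced from A549 cells, an established human lung cancer line, after transduction with a lentivirus for GPD1 or with a blank lentivirus, and after culture with 10 mM metformin or without it. GPD1 is the cytosolic glycerol-3-phosphate dehydrogenase, which uses NADH to turn dihydroxyacetone phosphate into glycerol-3-phosphate. Metformin is a biguanide drug for diabetes that inhibits complex I of the respiratory chain. The study asked how GPD1 acts on the growth of cancer cells with metformin and without it. The series holds 24 samples, of which the 12 of A549 were compared, as 4 groups of 3 libraries (vector untreated, vector metformin, GPD1 untreated and GPD1 metformin). The 12 samples of 786-O, a kidney cancer line, were not analysed here. The values are read as FPKM, and they cannot be told apart from RPKM because the table names no unit. The steps between low values correspond to a depth of 13.3 to 18.0 M reads or fragments per library, so that 1 read on 1 kb of exon is worth 0.0556 to 0.0753 FPKM. The genes above 0 numbered 23472 to 23993 in GPD1 metformin libraries, 24688 to 25099 in vector metformin libraries and 25471 to 26739 in untreated libraries. The depths of these libraries overlapped, and the cause of the difference was not tested. Log2 fold changes were taken on log2(FPKM + 1) and understate the fold of weakly expressed genes, so folds are ratios of the group means in FPKM. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The sample names show no separate transductions either. What is called an effect of GPD1 may therefore include other differences between the transduced populations. Across the 12 libraries the first principal component held 66.1% of the variance and parted metformin-treated from untreated cells. The second (19.2%) parted GPD1 from vector cells, at -33.31 to -30.98 against 30.01 to 35.76 under metformin. Without the drug it parted them less, at -7.58 to -6.58 against 5.37 to 7.61. The third (4.4%) parted GPD1 from vector cells mainly without the drug.

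The transgene was measured first, as a check of the labels. GPD1 (ENSG00000167588, chromosome 12, GRCh38 positions 50103819 to 50111319) stood at 0.0770 ± 0.0323 FPKM in untreated vector cells and at 15.8 ± 0.855 FPKM in untreated GPD1 cells (mean ± SD, n = 3), a 206-fold difference with a log2 fold change of 3.97 (SE 0.05; limma, adjusted p = 5.2e-12). Under metformin it stood at 0.0538 ± 0.0251 FPKM in vector cells and at 13.5 ± 0.270 FPKM in GPD1 cells, a 251-fold difference with a log2 fold change of 3.78 (SE 0.05; limma, adjusted p = 6.9e-12). The vector libraries held between 0.0250 and 0.103 FPKM, or 2 to 10 of the steps read as single reads. Metformin changed GPD1 by -0.03 log2 units in vector cells (SE 0.05; limma, adjusted p = 0.586) and by -0.22 in GPD1 cells (SE 0.05; limma, adjusted p = 0.00232). The second difference turned with the scaling, to 0.10 with median-ratio factors (limma, adjusted p = 0.114) and to 0.23 with upper-quartile factors (limma, adjusted p = 0.00217), and was -0.58 with totals taken without mitochondrial genes (limma, adjusted p = 2.2e-06).

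**Figure D1:**
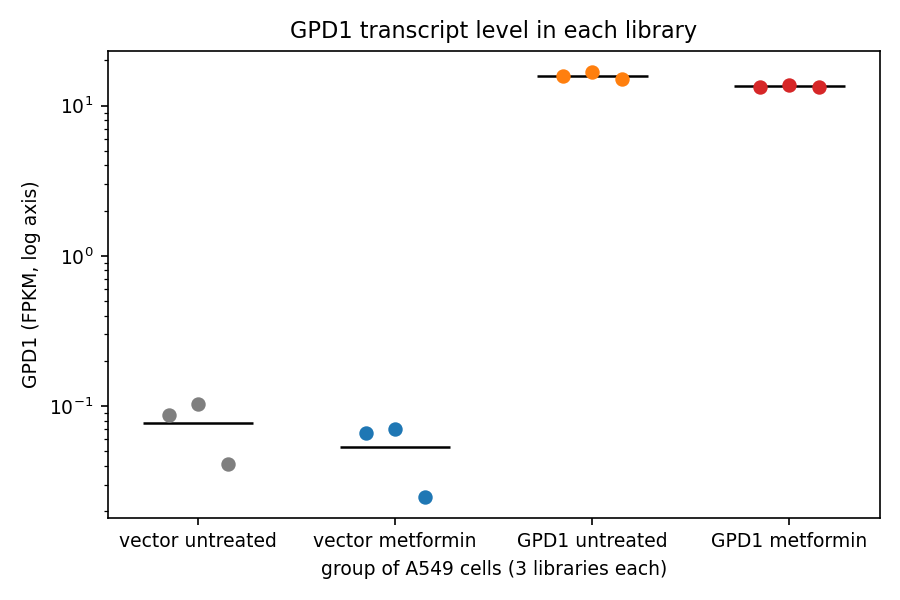
GPD1 level in FPKM (log axis) in each of the 12 libraries (points) with the mean of each group of 3 (lines). The 6 vector libraries lie between 0.0250 and 0.103 FPKM and the 6 GPD1 libraries between 13.3 and 16.8 FPKM.

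The first comparison asked what metformin changed in vector cells. DUSP5, a phosphatase that inactivates ERK, rose 27.0-fold from 16.4 ± 0.509 to 443.5 ± 25.3 FPKM (mean ± SD, n = 3 each), a log2 fold change of 4.67 (SE 0.05; limma, adjusted p = 7.7e-13). GDF15, a cytokine secreted by stressed cells, rose 19.9-fold from 34.8 ± 2.43 to 691 ± 58.8 FPKM. DDIT3, which encodes the stress transcription factor CHOP, rose 19.8-fold from 1.72 ± 0.0554 to 33.9 ± 2.07 FPKM, and PTGS2 (cyclooxygenase 2) rose 14.5-fold. PIM3 rose 16.9-fold, HES4 17.9-fold, TMEM158 17.4-fold and NR1D1, a circadian repressor, 12.1-fold. The immediate-early transcription factors FOS and EGR1 fell 37.9-fold and 22.6-fold, EGR1 from 56.0 ± 1.98 to 2.48 ± 0.305 FPKM. SPC25 and CENPF, which act at the kinetochore, fell 24-fold and 9.83-fold, the proliferation marker MKI67 9.68-fold, the flap endonuclease FEN1 9.13-fold and MT-CO2, a cytochrome c oxidase subunit, 8.47-fold. Each of these 15 genes had an adjusted p of 1.6e-09 or less (limma), and its 3 treated libraries all lay on the same side of the 3 untreated ones. MT-CYB was listed at 3347, 3197 and 3279 FPKM without the drug and at 240.1, 229.4 and 232.8 FPKM with it.

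In all, 9411 of 12607 tested genes passed (limma, Benjamini-Hochberg), 3948 higher and 5463 lower, among them 1079 higher and 1432 lower by at least 1 log2 unit. The higher share of 42% was 55.7% with median-ratio factors, 56.2% with upper-quartile factors and 27.8% with totals taken without mitochondrial genes, while the median of all genes went from -0.10 to 0.09, 0.10 and -0.34. List medians called relative are therefore taken against the median of all tested genes, and all other list medians are as deposited.

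The mitosis, DNA replication and mitochondrial genome lists fell with metformin in vector cells, while the nuclear subunits of complex I did not pass (10 risen and 11 fallen; camera, adjusted p = 0.563). All 22 tested genes of the mitosis list fell, with a relative median of -1.47 (camera, adjusted p = 9.4e-09). That call held with an estimated correlation (adjusted p = 0.0168 with an estimated correlation). KIF11, a spindle motor, fell 8.88-fold and BUB1, a checkpoint kinase, 3.24-fold. Of 28 DNA replication genes, 27 fell and 1 rose, with a relative median of -1.29 (camera, adjusted p = 2.3e-08, but adjusted p = 0.0803 with an estimated correlation). The helicase subunit MCM3 fell 5.67-fold, GINS1 6.94-fold and the licensing factor CDC6 6.48-fold. All 13 transcripts of the mitochondrial genome fell, with a relative median of -2.36 (camera, adjusted p = 2.2e-05, but adjusted p = 0.259 with an estimated correlation). MT-CO3 fell 7.05-fold, MT-ATP8 7.42-fold and MT-ATP6 5.52-fold. The call of MT-CYB itself (limma, adjusted p = 0.0471) ended without any 1 of the 9 libraries outside the GPD1 metformin group, at an adjusted p of 0.0596 to 0.0916 and a log2 fold change of -3.82 to -3.79, against -3.80 with all. It also ended with median-ratio factors (limma, adjusted p = 0.0658), upper-quartile factors (0.0696), no filter (0.0932) and a pseudocount of 0.1 (0.15). The variance is shared by the 4 groups, and in a fit of the vector groups alone the adjusted p was 2.5e-07 (limma).

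Another 6 lists rose in the same cells, while fatty acid synthesis did not pass (5 risen and 7 fallen; camera, adjusted p = 0.876). Of 16 ATF4 stress response genes, 13 rose and 3 fell, with a relative median of 1.35 (camera, adjusted p = 8.7e-05, and adjusted p = 0.0311 with an estimated correlation). ATF4 itself rose 2.96-fold and CEBPB 6.27-fold. Of 20 p53 targets, 16 rose and 3 fell (camera, adjusted p = 2.3e-05, but adjusted p = 0.155 with an estimated correlation), among them the apoptosis gene BBC3, 9.21-fold, and AEN, 5.56-fold. GDF15 belongs to both lists. Of 21 genes of cholesterol synthesis and uptake, 13 rose and 3 fell (camera, adjusted p = 0.00311, but adjusted p = 0.155 with an estimated correlation), with MSMO1 up 4.89-fold and FDFT1 3.06-fold. Of 12 hypoxia response genes, 8 rose and 1 fell (camera, adjusted p = 0.00695, but adjusted p = 0.102 with an estimated correlation), with DDIT4, an inhibitor of mTORC1, up 4.36-fold and VEGFA 3.03-fold. Of 52 cytosolic ribosomal proteins, 50 rose and 1 fell, with a relative median of 0.70 (camera, adjusted p = 9.5e-11, but adjusted p = 0.102 with an estimated correlation), RPS25 by 1.94-fold. Of 17 autophagy and lysosome genes, 11 rose and 4 fell (camera, adjusted p = 0.0248, but adjusted p = 0.102 with an estimated correlation), with the protease CTSB up 3-fold. The autophagy call ended with median-ratio factors (camera, adjusted p = 0.0586) and with upper-quartile factors (camera, adjusted p = 0.0595), the highest of the camera alternatives that kept all libraries and the preset correlation, whose lowest was 7.8e-04. The relative median of that list was 0.60 to 0.65 over the scalings. For each of these 9 lists the counts adjusted over the list alone were the same as those over all genes tested.

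The second comparison asked what metformin changed in cells that overexpress GPD1. GDF15 rose 21.9-fold from 23.2 ± 1.14 to 506 ± 22.8 FPKM (mean ± SD, n = 3 each), a log2 fold change of 4.39 (SE 0.07; limma, adjusted p = 2.7e-11). PPP1R15A, which directs dephosphorylation of eIF2 alpha, rose 15-fold from 23.3 ± 0.400 to 351 ± 6.48 FPKM. The HSP70 genes HSPA1A and HSPA1B, near-identical copies whose reads may be shared, rose 13.2-fold and 15.7-fold, HSPA1A from 49.5 ± 1.98 to 652 ± 80.4 FPKM. PIM3 rose 19.0-fold, HES4 19.3-fold, DUSP5 14.5-fold and TMEM265 30.9-fold. MT-ND3 fell 36.1-fold from 2027 ± 162 to 56.1 ± 1.05 FPKM, a log2 fold change of -5.15 (SE 0.16; limma, adjusted p = 8.5e-10). MT-CO2 fell 16.4-fold, MT-ND5 15.9-fold, MT-ND1 15.7-fold and MT-ATP8 11.8-fold, and FEN1 fell 31.7-fold to 1.07 ± 0.184 FPKM. Each of these 14 genes had an adjusted p of 1.9e-06 or less (limma). MT-CYB was listed at 191, 0 and 0 FPKM with metformin, and the readthrough gene SENP3-EIF4A1, which shares sequence with SENP3 and EIF4A1, at 0, 5.37 and 0 FPKM.

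In all, 9349 genes passed (limma, Benjamini-Hochberg), 3293 higher and 6056 lower. The higher share of 35.2% was 53.7% with median-ratio factors, 61.6% with upper-quartile factors and 17.3% with totals taken without mitochondrial genes, while the median of all genes went from -0.20 to 0.06, 0.16 and -0.49.

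All 13 mitochondrial genome transcripts fell with metformin in GPD1 cells, with a relative median of -3.33 (camera, adjusted p = 3.5e-06, but adjusted p = 0.16 with an estimated correlation). Mitochondrial genes held 30.2% to 32.3% of all FPKM in untreated GPD1 cells and 10.3% to 11.4% with metformin, against 33.0% to 33.2% and 13.7% to 14.9% in vector cells. Of 22 mitosis genes 21 fell (camera, adjusted p = 3.5e-06, and adjusted p = 0.0361 with an estimated correlation), CENPF by 5.80-fold and KIF11 by 4.11-fold. Of 28 DNA replication genes 27 fell and 1 rose (camera, adjusted p = 1.5e-06, but adjusted p = 0.0706 with an estimated correlation), MCM3 by 4.71-fold. Of 19 ribosome biogenesis genes 16 fell and 2 rose, with a relative median of -0.42 (camera, adjusted p = 0.0365, but adjusted p = 0.38 with an estimated correlation). The nucleolar protein genes NOP56 and NOP58 fell 7.72-fold and 4.64-fold, and POLR1A, the largest subunit of RNA polymerase I, 5.24-fold. That call ended with totals taken without mitochondrial genes (camera, adjusted p = 0.132) and among protein-coding genes alone (camera, adjusted p = 0.0698), in a range of 4.3e-04 to 0.132 over the same kind of alternatives. The relative median of ribosome biogenesis was -0.44 to -0.35 over the scalings.

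**Figure D2:**
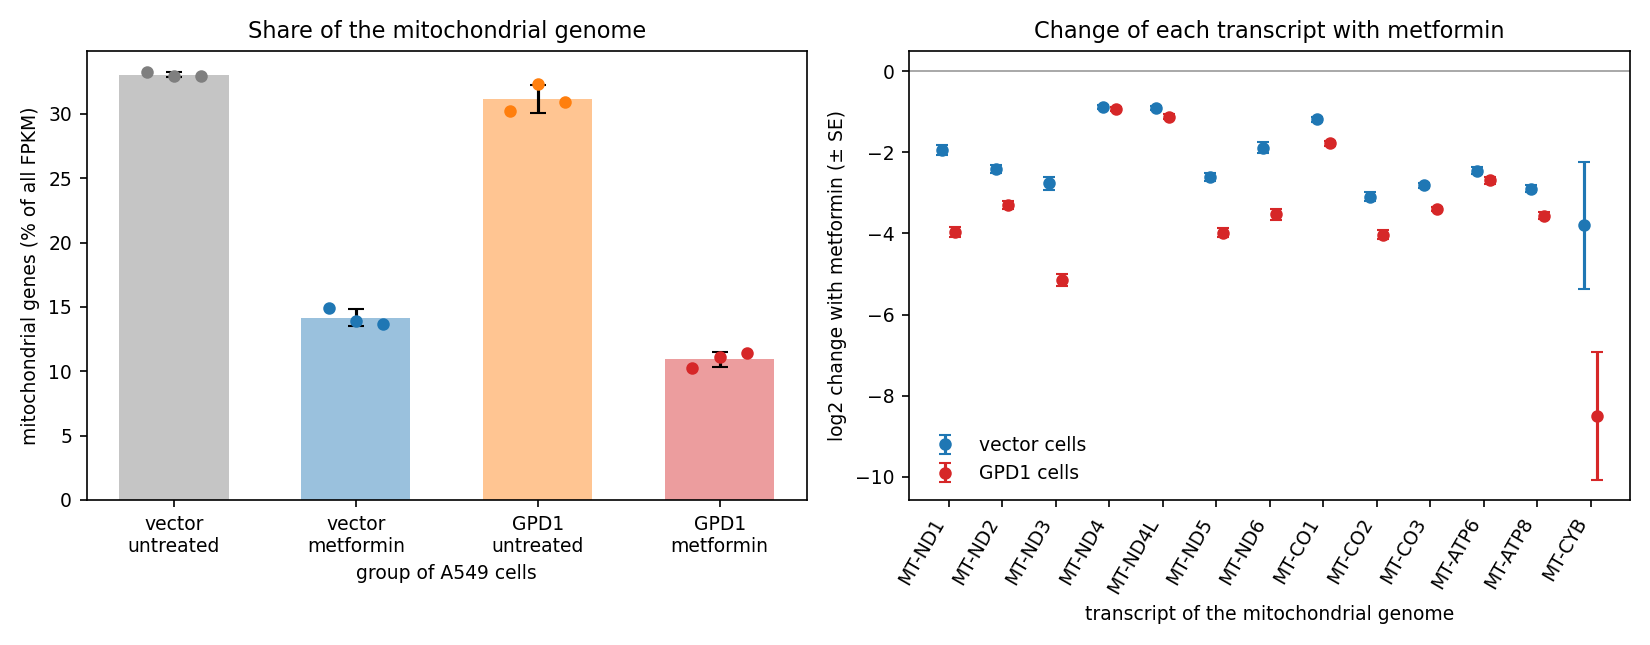
Left, percent of all FPKM from mitochondrial genes in each library (points), with group means (bars) and SDs (error bars, n = 3), from 33.2% at most in untreated vector cells to 10.3% at least in GPD1 cells with metformin. Right, log2 change of each of the 13 transcripts with metformin (± SE) in vector and GPD1 cells, all below 0, where MT-CYB was listed at 0 in 2 GPD1 libraries.

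Another 9 lists rose with metformin in GPD1 cells. Of 16 ATF4 stress response genes 11 rose and 3 fell, with a relative median of 1.59 (camera, adjusted p = 1.7e-04, and adjusted p = 0.0361 with an estimated correlation). Of 52 cytosolic ribosomal proteins 51 rose and 0 fell, with a relative median of 1.08 (camera, adjusted p = 1.3e-19, and adjusted p = 0.0433 with an estimated correlation), RPL13 by 2.21-fold. Of 20 p53 targets 13 rose and 4 fell (camera, adjusted p = 4.7e-04, but adjusted p = 0.16 with an estimated correlation), with the cell cycle inhibitor CDKN1A up 5.29-fold. Of 13 NF-kB and cytokine genes 10 rose and 3 fell (camera, adjusted p = 0.00276, but adjusted p = 0.134 with an estimated correlation), with RELB up 5.97-fold and LIF 3.52-fold. Of 21 genes of cholesterol synthesis and uptake 13 rose and 3 fell (camera, adjusted p = 2.1e-04, but adjusted p = 0.0799 with an estimated correlation), and of 15 fatty acid synthesis genes 10 rose and 3 fell, the latter 4 when adjusted over the list alone (camera, adjusted p = 0.0126, but adjusted p = 0.16 with an estimated correlation). The desaturase SCD rose 3.02-fold. Of 12 hypoxia response genes 9 rose and 1 fell (camera, adjusted p = 0.00217, but adjusted p = 0.0528 with an estimated correlation), and of 17 autophagy and lysosome genes 12 rose and 4 fell (camera, adjusted p = 0.0042, but adjusted p = 0.0528 with an estimated correlation). Of 37 nuclear subunits of complex I 19 rose and 7 fell, with a relative median of 0.38 (camera, adjusted p = 0.00586, but adjusted p = 0.104 with an estimated correlation), NDUFV2 by 1.55-fold. Adjusted over the list alone, the other counts of the 13 called lists were the same. Transcript length moved with this comparison, with a Spearman's rho of -0.27 across 10134 genes, a median change of 0.05 up to 2331 bases and one of -0.42 from 5348 bases. The NF-kB call ended with upper-quartile factors (camera, adjusted p = 0.0693), while its relative median was 1.07 to 1.13 over the scalings. With totals taken without mitochondrial genes the complex I and fatty acid synthesis calls ended (camera, adjusted p = 0.201 for each). Their medians, 0.19 and 0.24, turned to -0.17 and -0.13 there, where the median of all genes went from -0.20 to -0.49. Relative to all genes these list medians stayed at 0.31 to 0.45 and 0.35 to 0.53 over the scalings. With the length trend removed the complex I call ended as well (camera, adjusted p = 0.254), with a median of 0.01 and 11 genes risen and 9 fallen. Over the same kind of alternatives the adjusted p ran from 2.6e-05 to 0.0693 for NF-kB, from 2.4e-04 to 0.254 for complex I and from 4.4e-04 to 0.201 for fatty acid synthesis (camera).

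The changes with metformin in both cell populations were set side by side across genes, which are not independent replicates. The log2 fold changes had a Pearson's r of 0.765 and a Spearman's rho of 0.744 over 12607 genes, from groups that share no library. Both comparisons called 2479 genes higher and 4425 lower, where independent lists of these sizes would share 1031 and 2624, and 799 genes were called in opposite directions.

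**Figure D3:**
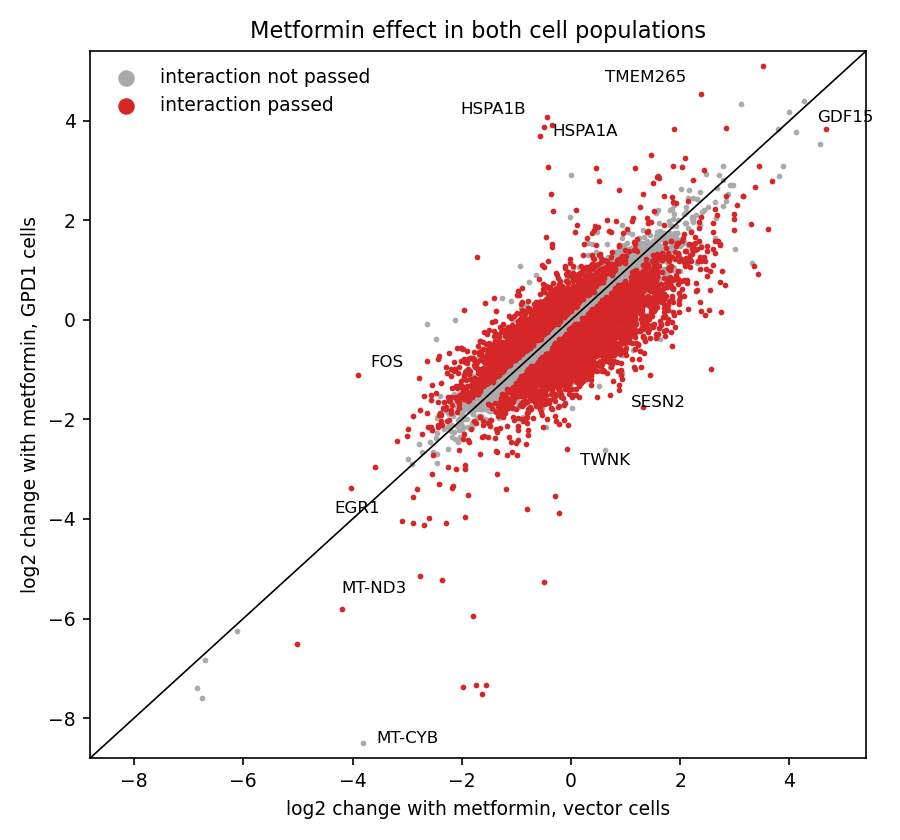
Log2 change with metformin of each of the 12607 tested genes (points) in vector cells (horizontal axis) and in GPD1 cells (vertical axis), with the line of equality. Red points passed the interaction test (5791 genes), among them HSPA1A and HSPA1B above the line and SESN2 and TWNK below it.

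The third comparison asked how GPD1 cells differed from vector cells without metformin. MUC5AC, a gel-forming mucin, was 18.8-fold higher, at 125 ± 6.76 against 6.66 ± 0.340 FPKM (mean ± SD, n = 3 each), a log2 fold change of 4.04 (SE 0.06; limma, adjusted p = 8.1e-12). The near-identical receptor genes NPY4R and NPY4R2, whose reads may be shared, were 13.7-fold and 13.8-fold higher. GPX2, a glutathione peroxidase, was 9.93-fold higher, cytidine deaminase (CDA) 14.7-fold, NAMPT, the rate-limiting enzyme of NAD salvage, 3.96-fold and the transglutaminase TGM2 3.72-fold. The largest falls were smaller, 3.28-fold in TENM3, 3.05-fold in CTXN1, 3.01-fold in CDCP1, 2.73-fold in the surface protein gene CD24, 2.58-fold in complement C5, 2.50-fold in the collagen genes COL4A1 and COL5A1 and 2.30-fold in SOX4. Each of these 15 genes had an adjusted p of 2.6e-06 or less (limma), and its libraries did not overlap between the groups.

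In all, 2688 of 12607 genes passed (limma, Benjamini-Hochberg), 1260 higher and 1428 lower, of which 66 and 57 differed by at least 1 log2 unit. The higher share of 46.9% was 52.8% with median-ratio factors, 55.5% with upper-quartile factors and 44.4% with totals taken without mitochondrial genes, so which direction held more genes turned with the scaling. NRF2 targets, genes of the antioxidant response, were the list with the smallest p. Of 21 members 14 rose and 1 fell, also when adjusted over the list alone, with a relative median of 0.35 (camera, adjusted p = 1.0e-08, and adjusted p = 0.0108 with an estimated correlation). The reductase AKR1C1 rose 2.99-fold, although its reads may be shared with its paralogs, the glutathione synthesis gene GCLM 1.57-fold and PGD of the pentose phosphate pathway 1.47-fold. Of 16 TCA cycle genes 5 rose and 0 fell, 6 when adjusted over the list alone, FH by 1.21-fold and PC by 1.31-fold (camera, adjusted p = 0.0312, but adjusted p = 0.223 with an estimated correlation). That call ended without GPD1 untreated replicate 1 (camera, adjusted p = 0.0627), and with all libraries kept it ran from 0.00171 to 0.0429. Of 28 DNA replication genes 11 fell and 1 rose, with 12 fallen when adjusted over the list alone and a relative median of -0.16 (camera, adjusted p = 0.00161, but adjusted p = 0.223 with an estimated correlation), MCM10 by 1.83-fold. Of 22 mitosis genes 5 fell and 1 rose, with 11 fallen when adjusted over the list alone and a relative median of -0.14 (camera, adjusted p = 0.00335, but adjusted p = 0.189 with an estimated correlation), TOP2A by 1.31-fold.

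The lists nearest to the enzyme itself did not pass against other genes in this comparison. Of 14 glycerolipid synthesis genes 6 rose and 2 fell, with a median of 0.16 (camera, adjusted p = 0.0896), and of 7 genes of the malate-aspartate shuttle, the other main carrier of cytosolic NADH electrons, 1 rose and 0 fell (camera, adjusted p = 0.556). The same counts passed when adjusted over the list alone. GPD2, the mitochondrial partner of GPD1 in the glycerol phosphate shuttle, was named after its values were seen, and it rose from 6.51 ± 0.121 to 10.97 ± 0.282 FPKM, a log2 fold change of 0.67 (limma, adjusted p = 2.3e-06). Neither list passed in another comparison, with a smallest adjusted p of 0.115 for the shuttle and metformin in vector cells (camera).

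The fourth comparison asked how GPD1 cells differed from vector cells under metformin, where more genes passed. The HSP70 genes HSPA1B and HSPA1A were 19.8-fold and 17.7-fold higher than in vector cells, the latter at 652 ± 80.4 against 36.8 ± 16.6 FPKM (mean ± SD, n = 3 each), a log2 fold change of 4.19 (SE 0.23; limma, adjusted p = 1.0e-07). MUC5AC was 20.8-fold higher, NPY4R 19.2-fold, NPY4R2 18.3-fold, the focal adhesion gene TNS4 15.7-fold and TMEM265 7.30-fold. TWNK, the helicase that replicates mitochondrial DNA, was 15.6-fold lower, at 0.620 ± 0.115 against 9.69 ± 2.56 FPKM, a log2 fold change of -2.70 (SE 0.14; limma, adjusted p = 8.9e-08). SESN2, a stress-induced inhibitor of mTORC1, was 8.24-fold lower, JMY 6.97-fold, the transcription factor KLF2 6.21-fold and MT-ND3 5.63-fold. The adjusted p of these genes was 9.3e-05 or less (limma). MYC was listed at 1.18, 18.2 and 1.2 FPKM in GPD1 cells and at 20.7, 20.7 and 26.2 FPKM in vector cells. Its call (limma, adjusted p = 0.0278) ended without GPD1 metformin replicate 1 or 3 (0.103 and 0.105) or vector metformin replicate 1, 2 or 3 (0.058, 0.0556 and 0.0704), and with no filter (0.0718). The log2 fold change of MYC, -2.37 with all libraries, was -1.85 and -1.86 without GPD1 metformin replicate 1 or 3. It was -2.43 to -2.265 without a vector metformin replicate. Without GPD1 metformin replicate 2 it was -3.42 (limma, adjusted p = 8.5e-04). MT-CYB and SENP3-EIF4A1 had uneven libraries as well. The call of MT-CYB (limma, adjusted p = 0.0127) ended without GPD1 metformin replicate 2 or 3 (0.053 and 0.0538), and in a fit of only the groups compared (0.0567). Its log2 fold change, -5.35 with all libraries, was -4.08 without replicate 2 or 3. Without GPD1 metformin replicate 1 it was -7.88 (limma, adjusted p = 3.7e-13).

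In all, 7566 genes passed (limma, Benjamini-Hochberg), 3157 higher and 4409 lower, of which 191 and 758 differed by at least 1 log2 unit. The higher share of 41.7% was 50.6% with median-ratio factors, 62.2% with upper-quartile factors and 32.6% with totals taken without mitochondrial genes, while the median of all genes went from -0.05 to 0.02, 0.13 and -0.12. Across genes the GPD1 effects without and with metformin had a Pearson's r of 0.306 and a Spearman's rho of 0.221, with 733 genes called higher in both and 742 lower in both, where independent lists would share 316 and 499, and 516 called in opposite directions.

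Under metformin 9 lists stood higher in GPD1 cells, while DNA replication did not pass (7 genes higher and 7 lower; camera, adjusted p = 0.633). Of 22 mitosis genes 17 were higher and 1 lower, 18 and 1 when adjusted over the list alone, with a relative median of 0.39 (camera, adjusted p = 1.8e-05, and adjusted p = 0.0489 with an estimated correlation), BUB1 by 2.32-fold. Of 21 NRF2 targets 14 were higher and 2 lower, 15 and 2 when adjusted over the list alone (camera, adjusted p = 1.1e-04, and adjusted p = 0.0489 with an estimated correlation), GCLM by 2.02-fold and TALDO1 by 1.70-fold. Of 37 complex I subunits 19 were higher and 1 lower, 18 and 1 when adjusted over the list alone (camera, adjusted p = 1.6e-04, and adjusted p = 0.0494 with an estimated correlation), NDUFA2 by 1.81-fold. Of 16 TCA cycle genes 10 were higher and 0 lower (camera, adjusted p = 5.0e-04, and adjusted p = 0.0494 with an estimated correlation), OGDH by 2.34-fold. Of 17 glycolysis genes 11 were higher and 2 lower, with a relative median of 0.48 (camera, adjusted p = 0.00146, but adjusted p = 0.228 with an estimated correlation), the lactate exporter SLC16A3 by 6.54-fold and ENO1 by 1.81-fold. Of 15 fatty acid synthesis genes 11 were higher and 1 lower (camera, adjusted p = 1.6e-04, but adjusted p = 0.076 with an estimated correlation), ACSL3 by 2.56-fold and ACLY by 1.61-fold. Of 10 tested interferon response genes 6 were higher and 1 lower (camera, adjusted p = 0.0178, but adjusted p = 0.188 with an estimated correlation), ISG15 by 6.67-fold. The other members of the interferon list lay below the filter and were not tested. Among them were IFIT1, MX1 and RSAD2, with means of 0.478, 0.0719 and 0.0728 FPKM. All 6 polyadenylated histone transcripts were higher (camera, adjusted p = 0.0092, but adjusted p = 0.081 with an estimated correlation), HIST1H2BK by 1.8-fold.

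Ribosome-related lists parted under metformin. Of 52 cytosolic ribosomal proteins 24 were higher and 0 lower in GPD1 cells, 21 and 0 when adjusted over the list alone, with a relative median of 0.26 (camera, adjusted p = 1.8e-05, but adjusted p = 0.225 with an estimated correlation), RPL24 by 1.21-fold. Of 19 ribosome biogenesis genes 15 were lower and 2 higher, with a relative median of -0.66 (camera, adjusted p = 0.00118, but adjusted p = 0.228 with an estimated correlation), NOP58 by 2.71-fold and NOP56 by 2.69-fold. Of 13 mitochondrial genome transcripts 11 were lower and 0 higher, 12 and 0 when adjusted over the list alone, with a relative median of -0.94 (camera, adjusted p = 1.8e-04, but adjusted p = 0.228 with an estimated correlation), MT-ND1 by 4.42-fold and MT-ND5 by 3.15-fold. For the lists with no such second count, the counts adjusted over the list alone were the same. Transcript length moved with this comparison too (Spearman's rho of -0.22 across 10134 genes).

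The last comparison asked whether the change with metformin differed between GPD1 and vector cells, as the change in GPD1 cells minus that in vector cells (interaction). HSPA1A went from 49.5 ± 1.98 to 652 ± 80.4 FPKM in GPD1 cells and from 51.7 ± 1.74 to 36.8 ± 16.6 FPKM in vector cells (mean ± SD, n = 3 each), an interaction of 4.25 (SE 0.32; limma, adjusted p = 3.8e-06), beside 4.38 for HSPA1B. FOS (2.80) went from 21.5 ± 1.82 to 9.55 ± 2.15 FPKM in GPD1 cells and from 23.1 ± 2.21 to 0.610 ± 0.181 FPKM in vector cells. The ubiquitin-like interferon gene ISG15 (2.26) went from 4.48 ± 0.466 to 36.6 ± 0.544 FPKM in GPD1 cells and from 3.52 ± 0.384 to 5.49 ± 0.603 FPKM in vector cells. TMEM265 (2.15), the collagen IV genes COL4A1 (1.92) and COL4A2 (1.85) and TNS4 (1.81) also lay higher. SESN2 (-2.29) lay lower, with 14.3 ± 0.837 FPKM in vector cells and 1.74 ± 0.166 FPKM in GPD1 cells under metformin, as did the antiproliferative gene BTG2 (-2.55), TWNK (-2.52), MT-ND3 (-2.38), KLF2 (-2.37), FAM102A (-2.24) and IFFO2 (-2.19). The adjusted p of these 15 genes was 0.0107 or less (limma).

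In all, 5791 of 12607 genes passed the interaction (limma, Benjamini-Hochberg), 2407 higher and 3384 lower. The higher share of 41.6% was 49.2% with median-ratio factors, 61.5% with upper-quartile factors and 32.1% with totals taken without mitochondrial genes, while the median of all genes went from -0.04 to 0.02, 0.12 and -0.11. Of the 6904 genes called with metformin in the same direction in both populations, 2866 passed, and their change was larger in GPD1 cells in 1178 (303 risen and 875 fallen) and smaller in 1688 (642 risen and 1046 fallen). This split is for the values as deposited and was not repeated with other scalings. As lists, mitosis and DNA replication had fallen less in GPD1 cells, mitosis in most of its genes and DNA replication in part of them. Of 22 mitosis genes 18 lay higher and 0 lower, 19 and 1 when adjusted over the list alone, with a relative median of 0.58 (camera, adjusted p = 8.5e-08, and adjusted p = 0.0218 with an estimated correlation), KIF11 by 0.97 and TOP2A by 0.97. Of 28 DNA replication genes 12 lay higher and 2 lower, 13 and 2 when adjusted over the list alone (camera, adjusted p = 0.0159, but adjusted p = 0.247 with an estimated correlation), with PCNA at 0.72. The DNA replication list was already lower in GPD1 cells without the drug (median -0.17) and did not pass between GPD1 and vector cells with it.

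The remaining lists parted into those lower and those higher in GPD1 cells. Of 13 mitochondrial genome transcripts 10 lay lower and 0 higher, with a relative median of -0.85 (camera, adjusted p = 4.1e-04, but adjusted p = 0.247 with an estimated correlation), MT-ND1 at -2.02 and MT-ND5 at -1.38. Of 19 ribosome biogenesis genes 12 lay lower and 1 higher, 12 and 2 when adjusted over the list alone (camera, adjusted p = 0.0159, but adjusted p = 0.257 with an estimated correlation). Of 20 p53 targets 10 lay lower and 2 higher (camera, adjusted p = 0.0461, but adjusted p = 0.347 with an estimated correlation), SESN1 at -1.40 and BBC3 at -0.87. Of 52 cytosolic ribosomal proteins 24 lay higher and 0 lower, 25 and 0 when adjusted over the list alone (camera, adjusted p = 5.7e-07, but adjusted p = 0.2 with an estimated correlation). Of 17 glycolysis genes 8 lay higher and 2 lower, 9 and 2 when adjusted over the list alone (camera, adjusted p = 0.0159, but adjusted p = 0.257 with an estimated correlation), with ENO1 at 0.55. Of 15 fatty acid synthesis genes 7 lay higher and 1 lower (camera, adjusted p = 0.0138, but adjusted p = 0.2 with an estimated correlation), with FADS2 at 0.93 and ACLY at 0.89. Of 10 tested interferon response genes 6 lay higher and 1 lower (camera, adjusted p = 0.0284, but adjusted p = 0.2 with an estimated correlation), a call that ended with no filter on low values (camera, adjusted p = 0.0523). Of 37 complex I subunits 8 lay higher and 1 lower, 4 and 1 when adjusted over the list alone (camera, adjusted p = 0.0178, but adjusted p = 0.2 with an estimated correlation), and of 16 TCA cycle genes 5 lay higher and 0 lower (camera, adjusted p = 0.0284, but adjusted p = 0.2 with an estimated correlation). Where no second count is given, that adjusted over the list alone was the same. Transcript length moved with the interaction (Spearman's rho of -0.21), and removing its trend ended the complex I and TCA cycle calls (camera, adjusted p = 0.122 and 0.103), as did totals taken without mitochondrial genes (camera, adjusted p = 0.0546 and 0.0807). The medians went from 0.127 to 0.07 and from 0.18 to 0.13 without the length trend, while relative to all genes they stayed at 0.17 to 0.21 and 0.20 to 0.26 over the scalings. The p53 call ended in 10 of 23 alternatives, among them 5 of the 12 that left out a library (camera), namely without GPD1 metformin replicate 1 (adjusted p = 0.0615), GPD1 untreated replicate 1 (0.051), vector metformin replicates 1 and 2 (0.0618 and 0.0646) and vector untreated replicate 3 (0.0677). With all libraries and the preset correlation kept, the adjusted p ran from 0.00329 to 0.0666 for p53 targets, from 0.00195 to 0.122 for complex I, from 0.00314 to 0.103 for the TCA cycle and from 0.0255 to 0.0523 for the interferon list (camera).

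**Figure D4:**
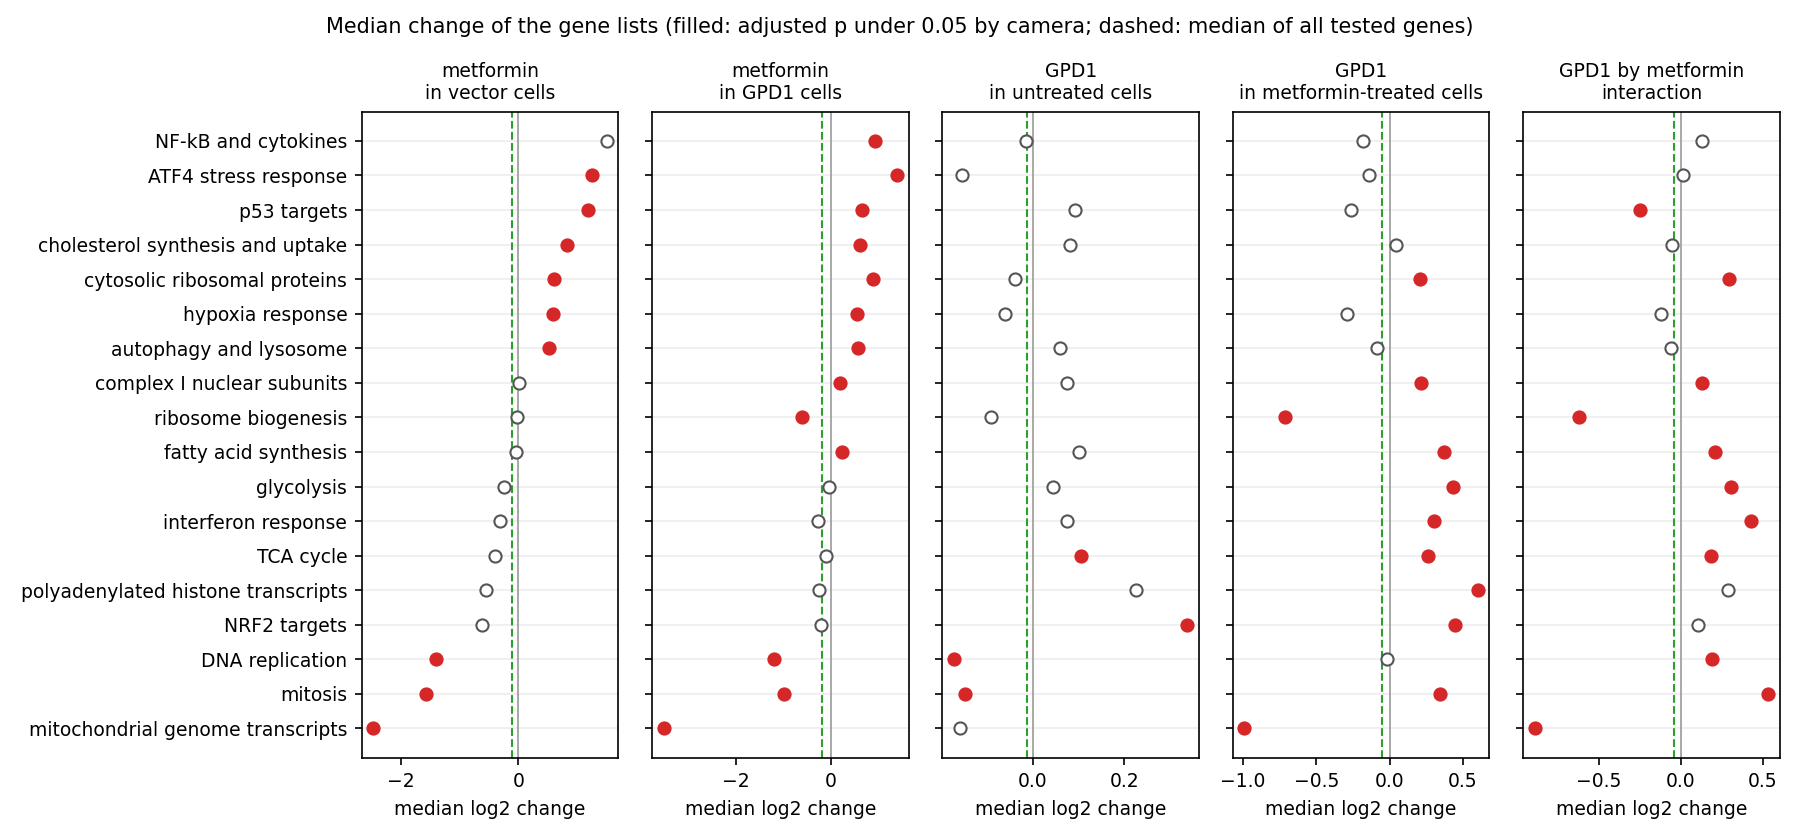
Median log2 change (points) of the 18 gene lists called in at least 1 of the 5 comparisons, with filled points at a camera adjusted p under 0.05 and a dashed line at the median of all tested genes. The mitochondrial genome list lies at -2.46 in vector cells and at -3.53 in GPD1 cells with metformin.

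Differences between GPD1 and vector cells were also laid out along the genome (GRCh38), in 403 windows of 25 neighbouring protein-coding genes. On chromosome 10, the medians of 3 of the 4 windows between positions 134465 and 45594906 lay at least 0.25 lower in GPD1 cells both without metformin and with it, with a median of -0.47 and -0.51 over their 75 genes, of which 67 and 62 were lower. The window skipped between them, from 16436943 to 27242130, had medians of -0.49 and -0.17. On chromosome 13 the median of 65 genes between 66302834 and 114327328 was higher (0.29 and 0.33), although 11 and 13 of them were lower. On chromosome 17 the median of 25 genes between 37084988 and 39451286 was lower (-0.28 and -0.35), with 24 and 17 of them lower. MCM10 lies in the chromosome 10 stretch, as do AKR1C1 and AKR1C3, which were higher in GPD1 cells against the direction of the stretch (1.55 and 0.60 without metformin). COL4A1 and COL4A2 lie in that of chromosome 13 and were lower without metformin, also against its direction (-1.27 and -1.11), and higher with it (0.65 and 0.74). Of the 10019 genes in windows 2411 differed without metformin, and of the 165 genes in these stretches 114 did, though the stretches were chosen for their differences.

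**Figure D5:**
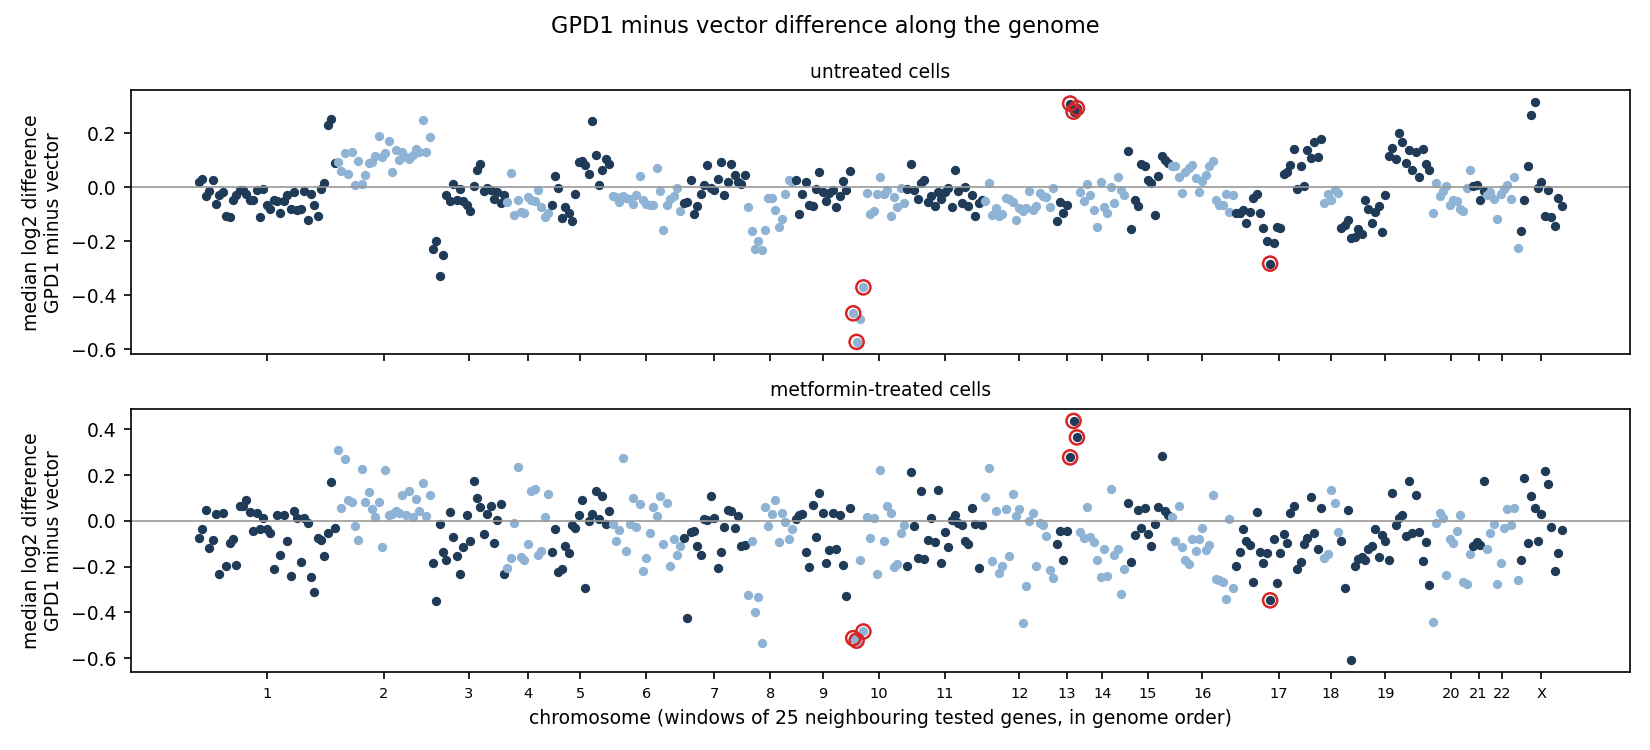
Median log2 difference between GPD1 and vector cells (points) in 403 windows of 25 neighbouring tested protein-coding genes, in genome order, without metformin (top) and with it (bottom). Red circles mark the windows at least 0.25 log2 units from 0 in the same direction in both, on chromosomes 10, 13 and 17.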

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

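The tests on transcript length and GC content, and the totals taken without mitochondrial genes, were chosen only after the results were seen. The interaction passed in 5791 of 12607 genes. Of 100 draws among the 200 possible splits of the GPD1 and vector labels, 1 gave as many genes, the real one, and the highest other gave 5034. Exchanging the GPD1 and vector labels in untreated cells, which was not among the draws and tests the sum of both GPD1 effects, gave 6731 genes, more than the real labels. Splits that mix GPD1 and vector libraries carry the GPD1 effect into the spread within groups, so the counts follow the structure of the 4 groups and give no level of chance for the interaction. For the 4 comparisons of 3 libraries with 3, 10 splits exist, too few for a share under 0.05. In each, 1 split gave as many genes, the real one, with 9411 against a highest other of 2 (metformin in vector cells), 9349 against 1 (metformin in GPD1 cells), 2688 against 5 (GPD1 without metformin) and 7566 against 2 (GPD1 with metformin).

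Mitochondrial genome transcripts fell further with metformin in GPD1 cells, with a median interaction of -0.89 as deposited. The excess was not shared evenly, as MT-ND3 had an interaction of -2.38 and MT-ND1 of -2.02, while MT-ND4 (-0.06) and MT-ATP6 (-0.23) did not pass (limma, adjusted p = 0.581 and 0.152), nor did MT-CYB with its uneven libraries (-4.70, SE 2.22; limma, adjusted p = 0.109). The tables argue against scaling and length as the source, since the median stayed at -0.67 in the nearest to 0 of 3 other scalings, and removal of the length trend gave -1.03. TWNK was low as well (interaction -2.52), but mitochondrial DNA and its transcription were not measured, so whether less of either contributes was not tested. The list call is open as well (camera, adjusted p = 4.1e-04, but adjusted p = 0.247 with an estimated correlation).

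Shorter transcripts rose against longer ones with metformin in GPD1 cells, with a Spearman's rho of -0.27 that was -0.25 after removal of the GC trend. The 3 GPD1 metformin libraries deviated from the gene means with a rho of -0.28, -0.27 and -0.31, vector metformin libraries with -0.04 to 0.04 and untreated ones with 0.14 to 0.19. After removal of the length trend the interaction call ended for complex I subunits (median as deposited from 0.127 to 0.07; camera, adjusted p = 0.122) and held with smaller medians for ribosomal proteins (from 0.29 to 0.18; camera, adjusted p = 1.2e-04) and mitosis (from 0.53 to 0.46; camera, adjusted p = 5.5e-08). With the values as deposited and an estimated correlation, the mitosis call passed and that of ribosomal proteins did not. RNA integrity or library preparation that differed by group could give such a trend, as could regulation of short transcripts, and these libraries do not separate them.

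The other lists had median interactions, as deposited, of 0.305 (glycolysis), 0.18 (TCA cycle), 0.21 (fatty acid synthesis), 0.19 (DNA replication), -0.25 (p53 targets), 0.43 (interferon response) and -0.62 (ribosome biogenesis). The genes with the largest interactions were HSPA1B (4.38), HSPA1A (4.25), FOS (2.80), ISG15 (2.26), TMEM265 (2.15), COL4A1 (1.92), COL4A2 (1.845) and TNS4 (1.81) upward. Downward they were BTG2 (-2.55), TWNK (-2.52), MT-ND3 (-2.38), KLF2 (-2.37), SESN2 (-2.29), FAM102A (-2.235) and IFFO2 (-2.19). SENP3-EIF4A1 had an interaction of -3.23 (limma, adjusted p = 0.0278) from uneven libraries, 14.35, 18.9 and 31.4 FPKM in untreated GPD1 cells against 0, 5.37 and 0 with metformin, and 67.3, 14.35 and 18.0 against 26.6, 25.95 and 13.3 in vector cells. Its call ended without GPD1 metformin replicate 1 or 3 (0.0653 and 0.0661), GPD1 untreated replicate 3 (0.0628), vector metformin replicate 1 or 2 (0.0599 and 0.0574) or vector untreated replicate 2 or 3 (0.0651 and 0.0612), and with no filter (0.0745). Without any 1 of these libraries the interaction itself was -3.09 to -2.79.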

How the results depend on the processing

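Of the alternatives, 5 were chosen only after the first results were seen. The number of genes changed with metformin in vector cells went from 9411 to 14315 with no filter, where more genes were tested. Asking for an absolute log2 fold change of at least 1, a stricter threshold, left 2511 (metformin in vector cells), 2161 (metformin in GPD1 cells), 123 (GPD1 without metformin), 949 (GPD1 with metformin) and 863 genes (interaction). Of 214 named results, 140 were called or not called as before. These include GPD1 with metformin in vector cells and the GPD1 interaction, which passed neither way. With replicate number as a block (replicate block) the counts were 9333, 9253, 2374, 7446 and 5643 in the same order. The numbers showed no pairing, as residuals correlated between -0.065 and 0.056 in 18 pairs with the same number and between -0.099 and 0.072 in 36 others. Leaving out 1 library gave 8977 to 9387, 8915 to 9388, 2078 to 2853, 6962 to 7509 and 5359 to 5766 genes. The change of GPD1 with metformin in GPD1 cells, -0.22, reversed to 0.096 with median-ratio and 0.23 with upper-quartile factors. The median of all genes in that comparison moved likewise, from -0.20 to 0.06 and 0.16. With a pseudocount of 0.1 the change of GPD1 was -0.23 (limma, adjusted p = 0.198) and its interaction -0.03 (limma, adjusted p = 0.923). The interaction of GPD1, -0.19 in the main fit (limma, adjusted p = 0.0523), reversed to 0.25 with upper-quartile factors (limma, adjusted p = 0.0179). That interaction passed without GPD1 untreated replicate 3 (-0.22; limma, adjusted p = 0.0407) or vector metformin replicate 3 (-0.21; limma, adjusted p = 0.0418), and also with the replicate block (limma, adjusted p = 0.0425), the length trend removed (0.0304), protein-coding genes alone (0.0451) and totals taken without mitochondrial genes (-0.53; limma, adjusted p = 3.0e-04), where the change in GPD1 cells was -0.58. The correlation of the metformin effects, 0.765, was 0.737 with no filter, of which the cause was not tested, and 0.748 to 0.775 with 1 library left out. P4HA2 and NDUFB1 in GPD1 cells did not pass with totals taken without mitochondrial genes. Without genes with uneven libraries the counts were 9416, 9353, 2705, 7565 and 5813. DESeq2, limma-voom, edgeR and a filter on counts per M were planned and not run, as they need counts.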

Other observations

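Lists that camera called in no comparison still held genes with large changes, which were named after their values were seen. HSPA5, the main chaperone of the endoplasmic reticulum, rose with metformin from 122 ± 2.88 to 523 ± 36.4 FPKM in vector cells and from 123 ± 2.14 to 260 ± 5.46 FPKM in GPD1 cells (mean ± SD, n = 3 each), an interaction of -1.01 (limma, adjusted p = 1.8e-06). PSAT1, an enzyme of serine synthesis, fell by 0.97 on the log2 scale in vector cells and rose by 0.58 in GPD1 cells, an interaction of 1.55 (limma, adjusted p = 3.0e-07). MTHFD2 of mitochondrial folate metabolism rose by 1.67 and 1.65. The amino acid transporter genes SLC7A11 and SLC38A2 fell by 1.36 and 1.05 in vector cells and by 1.46 and 2.01 in GPD1 cells. SLC7A11 also belongs to the ATF4 stress response and NRF2 target lists, which camera did call. Its falls went against the rise of the ATF4 list with metformin. FN1 rose by 1.21 and 1.27, and the cadherin gene CDH1 fell by 1.53 in vector cells and by 0.28 in GPD1 cells, an interaction of 1.25 (limma, adjusted p = 6.9e-05).

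The lists themselves did not pass with the values as deposited, with these smallest adjusted p over the 5 comparisons (camera). Fatty acid oxidation reached 0.0784 (interaction, 5 of 15 genes higher and 1 lower), serine and one-carbon synthesis 0.0724 (metformin in GPD1 cells, 7 of 10 risen and 3 fallen) and aminoacyl-tRNA synthetases 0.0733 (GPD1 without metformin, 1 of 18 risen and 8 fallen, 2 and 8 when adjusted over the list alone). ER chaperones reached 0.143 (metformin in GPD1 cells, 8 of 18 risen and 6 fallen) and amino acid transporters 0.214 (metformin in vector cells, 1 of 9 risen and 6 fallen). Epithelial genes reached 0.0629 (GPD1 with metformin, 6 of 8 higher and 1 lower, 7 and 1 when adjusted over the list alone), mesenchymal genes 0.0884 (interaction, 5 of 13 higher and 0 lower) and metallothioneins 0.0774 (interaction, 2 of 3 higher). With the length trend removed, an alternative chosen after the results were seen, 2 of these lists passed with metformin in GPD1 cells, aminoacyl-tRNA synthetases (10 risen and 5 fallen; camera, adjusted p = 0.0149) and serine and one-carbon synthesis (6 risen and 2 fallen; camera, adjusted p = 0.0481), as did fatty acid synthesis for GPD1 without metformin (camera, adjusted p = 0.0459, against 0.0593 as deposited). These calls are for the preset correlation only. Otherwise the counts as deposited were the same when adjusted over the list alone. With metformin in vector cells the median and mean of 5 of these lists had opposite signs, 0.30 and -0.14 for epithelial genes, 0.22 and -0.04 for serine and one-carbon synthesis, 0.32 and -0.03 for metallothioneins, -0.04 and 0.14 for aminoacyl-tRNA synthetases and -0.017 and 0.003 for mesenchymal genes. Of 11 lung lineage genes 1, ABCA3, was expressed enough to be tested (camera, smallest adjusted p = 0.158), and of 10 kidney lineage genes 4 were (camera, smallest adjusted p = 0.0676).

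The window test and the removal of length and GC trends were chosen only after the results were seen. Differences between GPD1 and vector cells ran in stretches of neighbouring genes, as window medians without and with metformin, from libraries not shared, correlated with an r of 0.512, against a highest value of 0.291 in 1000 shuffles of gene order. Removal of the GC trend left 0.514 (highest shuffle 0.338) and removal of the length trend 0.531 (0.338), which argues against both as the source. A difference in copy number or another regional difference between the transduced populations is a candidate explanation for the stretches on chromosomes 10, 13 and 17, but no DNA was examined. Shifts over neighbouring windows also lay outside these stretches, where a window missed 0.25 without metformin or with it. For example, medians in all windows of chromosome 2 were 0.01 to 0.25 without metformin, but -0.11 to 0.31 with it. They were -0.33 to -0.20 without and -0.35 to -0.01 with it in the first 4 windows of chromosome 3. In the first 5 of chromosome 8 they were -0.23 to -0.07 without and -0.53 to -0.09 with it. On chromosome 19 they were -0.19 to -0.03 without metformin up to position 32587452 and 0.04 to 0.20 beyond it. With metformin these ranges were -0.61 to 0.05 and -0.28 to 0.175. The 114 of 2411 calls inside the stretches therefore leave out such shifts, and how many GPD1 differences are regional stays open.

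Some genes had uneven libraries, as 64 of 12607 tested genes differed at least 5 times between libraries of a group, 15 of them with 0 in 1 library and at least 5 FPKM in another. MYC was listed at 0.667, 0.665 and 7.80 FPKM in untreated vector cells and at 0.868, 0.579 and 0.622 FPKM in untreated GPD1 cells.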
